A study of Mus musculus with 44 samples.

How the data were processed

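Messenger RNA of sorted mouse OT-I CD8 T cells was measured in 44 libraries, held in 4 tables: naive cells, cells from day 3 of infection, cells kept with OP9 feeder cells, and cells transduced with an empty or a BATF retrovirus. Per the labels' protocols, RNA was taken up in TRIzol and libraries were made with a kit that selects polyadenylated RNA. The cells sorted per library numbered 600000 to 3000000 for naive cells, 19000 to 110000 on day 3, 100000 in the co-culture and 60000 to 100000 after transduction, per the labels. Naive and day 3 samples come from 3 experiments each, and the labels do not say which sample is from which. The co-culture samples and the transduced samples come from 1 experiment each. All 44 sample columns were matched to a labelled sample by the table, group and replicate number in their names.

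The submitters' processing notes name Trimmomatic 0.35 and 0.39, STAR 2.5.1b and 2.7.8a, RSEM, featureCounts, DESeq2 1.16.1 and 1.24.0 and the mouse build GRCm38 (mm10). They give no role per table, so which set of versions made which table is not known. The authors' deposited values are a signal per gene and library: read counts divided by 1 factor per library, so that libraries of unequal depth share a scale. In every library 100% of the values above 0 were whole multiples of 1 step, with a tolerance of 0.05 of a step, and reads were recovered by dividing by that step. The deposited log2 fold changes of 3 tables are the authors' DESeq2 estimates, per the file headers. The deposited p-value and its adjusted form are also DESeq2's, per the file headers, and are quoted only where said. The naive and day 3 tables were scaled together by the authors, as their mean over 22 libraries shows. The other tables have scales of their own, so groups were tested within a table. Genes carry Ensembl identifiers. The transduction table has no symbols, and 52261 of its 55487 identifiers took theirs from the co-culture table, while the naive and day 3 tables have 50599 each. A spreadsheet had turned 27 symbols into dates, and these were restored. Coordinates are those of GRCm38. The counts are per gene. How reads that fit several genes were counted is not stated, so values of near-identical genes are uncertain.

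The design was fixed before the data were examined: the comparisons, tests, gene lists, the rule for named genes and most alternatives. It assumed normalized values. The test was therefore limma 3.58.1 (R 4.3.3) with a mean-variance trend on log2 of the normalized count plus 1, for genes with a mean of at least 10 over the libraries of the fit. P values were two-sided and adjusted by Benjamini-Hochberg, and 0.05 was the threshold. Log2 fold changes come from this fit, and fold changes are 2 to that power. The 16 transduction libraries were fitted together with 1 shared spread. The other comparisons used the libraries of their own 2 groups. No covariate or block was in the fit. The labels name none, apart from another tissue for OP9-DLL4 replicate 3, which the fit did not include. Tests on the recovered reads, by edgeR 4.0.16 with its quasi-likelihood test and by DESeq2 1.42.0, are alternatives.

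The 28 gene lists hold 670 genes. Lists with at least 5 tested genes were tested with camera at a preset correlation of 0.01 between genes, adjusted over the lists of a comparison. The same test with an estimated correlation stands beside it, and fry was an alternative. Counts adjusted over the list alone use the p values of the list's members. The day 3 sets hold genes with an adjusted p under 0.05 and an absolute log2 fold change of at least 0.58, at most 500 per direction. Overlaps of calls were tested with Fisher's exact test. For comparisons that share control libraries, 20 simulations of unchanged groups and a division of the controls were run.

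Named genes follow a rule. It takes Notch1, Notch2 and Batf in every comparison. It takes the 8 higher and 8 lower genes of largest log2 fold change among those that passed with a mean of at least 50 in the higher group and no overlap between groups. Predicted genes, receptor segments and pseudogenes were left out of that part. It also takes up to 4 members of smallest p per list. The text gives a part of these, and 1 gene that the rule names is not reported here. Dtx1 and Ifi27l2a in the co-culture are the 2 genes that passed there. An interaction has no overlap to test, so there the rule was applied without that condition.

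The fits were tested on simulated data with 200 changed genes, in 5 simulations per comparison. Of genes changed 2-fold, limma recovered 19.0% at naive depth and spread (11603 genes), 91.4% for day 3 (11274 genes), 64.0% for the co-culture (11470 genes) and 92.9% for KO Empty against WT Empty (11627 genes). At 4-fold these were 87.1%, 99.7%, 90.1% and 100%. Among the genes called, 8.03%, 5.77%, 7.1% and 5.4% had not been changed. A changed list was called in 5 of 5 simulations of each comparison, and 0 of 100 unchanged lists were called by camera in limma. The simulated genes varied independently and the lists were random draws. These list counts therefore do not test camera where the genes of a list vary together. The shares of genes recovered may likewise not hold in real libraries, where genes vary together. In the real naive libraries Notch1 was 4.52-fold lower with no overlap between groups, at adjusted p = 0.609 in limma. Other settings tried were pseudocounts, filters, scalings, weights, a replicate block, leaving out each library in turn, other tools, and other splits of the libraries, of which at most 100 were drawn.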

Results

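Messenger RNA was sequenced from mouse OT-I cells, CD8 T cells whose transgenic receptor recognises a peptide of ovalbumin, either wild type (WT) or labelled as lacking the Notch receptors Notch1 and Notch2 (KO). The 44 libraries fall into 10 groups held in 4 deposited tables. Naive cells sorted from lymph nodes and spleen gave 3 WT and 3 KO libraries. Day 3 cells had been transferred into congenic mice infected with Listeria that express ovalbumin. They were sorted as CD44-positive from the spleen after 72 hours and gave 8 WT and 8 KO libraries. Cells activated in culture and then kept on OP9 stromal feeder cells, or on OP9 cells that display the Notch ligand DLL4, gave 3 libraries each and were sorted on day 5. Of these 6, OP9-DLL4 replicate 3 is labelled as spleen and the others as lymph nodes. In the last table, WT and KO cells received an empty retrovirus or one carrying the transcription factor BATF. They were transferred and infected, then sorted at 72 hours by GFP. The groups WT Empty, WT Batf, KO Empty and KO Batf have 4 libraries each.

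The reads recovered per library numbered 10017799 to 15797496 in the naive table and 11788039 to 17895766 on day 3. They numbered 9253892 to 12733320 in the co-culture and 14923857 to 19293438 in the transduction table. Values are the authors' deposited normalized counts as mean ± SD over libraries. Log2 fold changes carry their standard error (SE), and a gene passed when its adjusted p in limma was under 0.05, two-sided. The labels call the libraries individual biological samples but do not say whether each came from a separate animal, so each p measures the spread between samples. The co-culture and the transduction come from 1 experiment each, so no p there measures the spread between experiments. On day 3 the 8 samples per genotype come from 3 experiments and were fitted as independent. A p there mixes the spread within and between experiments.

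Notch1 (ENSMUSG00000026923, GRCm38/mm10 chromosome 2, 26457903 to 26516663) stood at 3783 ± 1208 normalized counts in naive WT and 829 ± 237 in naive KO cells (n = 3 each). On day 3 it fell from 2841 ± 410 to 284 ± 81.8 (n = 8 each). In the transduced cells it stood at 2419 ± 44.9 in WT Empty, 2320 ± 46.6 in WT Batf, 523 ± 30.7 in KO Empty and 426 ± 24.9 in KO Batf (n = 4 each). Notch2 (ENSMUSG00000027878, chromosome 3, 98013527 to 98150361) stood at 1043 ± 414 and 1173 ± 112 in naive WT and KO cells and at 653 ± 119 and 530 ± 139 on day 3. It stood at 1216 ± 43.3, 1151 ± 37.0, 964 ± 43.8 and 893 ± 41.0 in WT Empty, WT Batf, KO Empty and KO Batf. The counts are per gene and not resolved by exon, so they do not show which part of either transcript was read, and the loss of Notch2 rests on the labels. On the feeder cells Notch1 stood at 1830 ± 138 without and 1597 ± 89.7 with DLL4, and Notch2 at 1288 ± 171 and 1057 ± 93.1 (n = 3 each). Batf (ENSMUSG00000034266, chromosome 12, 85686669 to 85709087) stood at 576 ± 115 and 553 ± 52.5 in naive WT and KO cells, and at 401 ± 51.6 and 435 ± 51.9 without and with DLL4. It rose from 1024 ± 36.2 in WT Empty to 3591 ± 72.1 in WT Batf, and from 871 ± 74.7 in KO Empty to 4059 ± 141 in KO Batf. Reads of the introduced and the endogenous Batf were not separated. Dtx1 (ENSMUSG00000029603, chromosome 5, 120680202 to 120711927), a gene induced by Notch signalling, stood at 4576 ± 1649 and 1218 ± 311 in naive WT and KO cells.

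**Figure D1:**
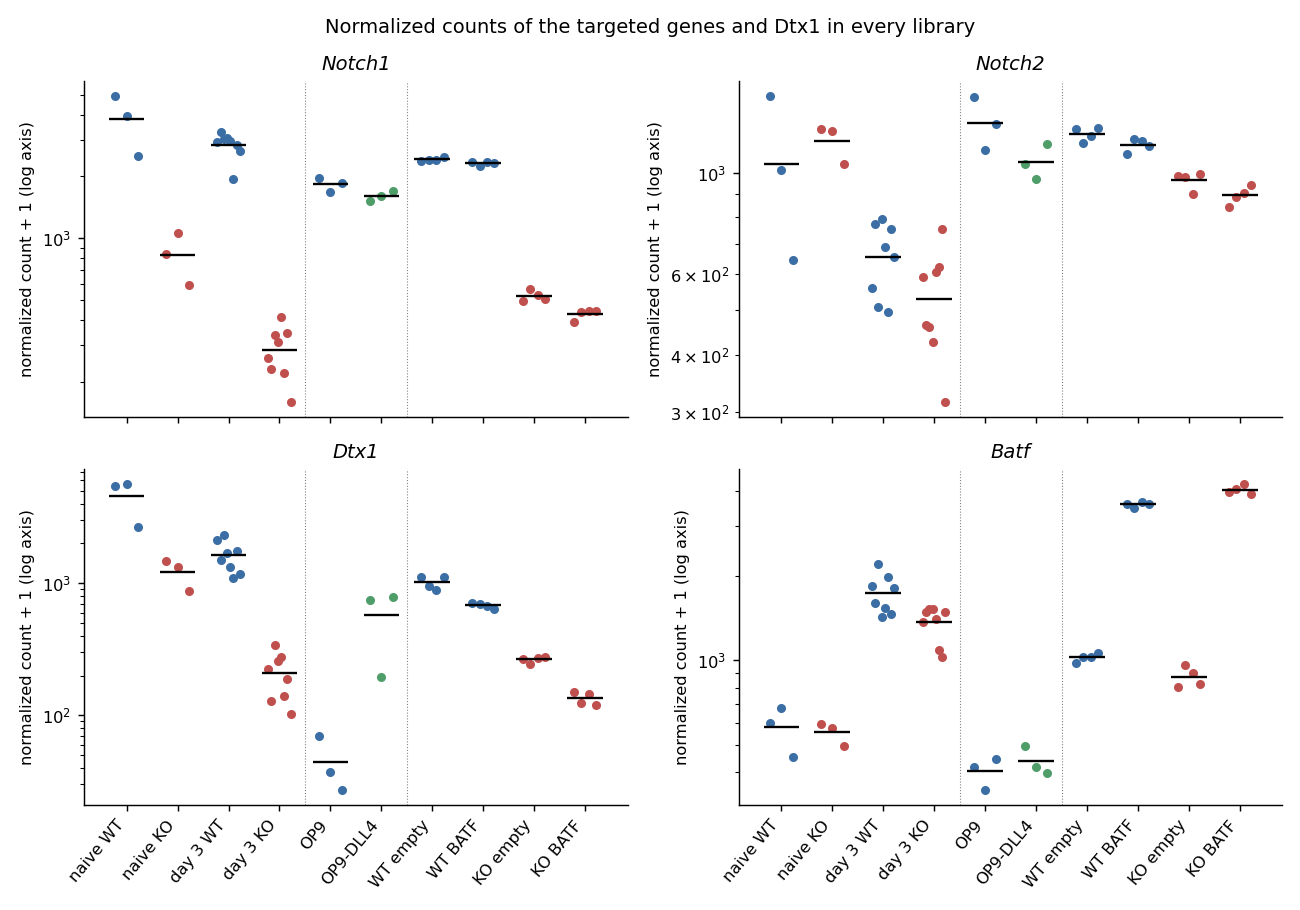
Normalized counts plus 1 on a log axis for Notch1, Notch2, Dtx1 and Batf in the 44 libraries, grouped on the horizontal axis by the 10 groups; each point is 1 library and each bar a group mean. Notch1 and Dtx1 lie lower in every KO group than in its WT partner, Dtx1 is higher on DLL4 feeders (573 against 43.6), and Batf is highest in the groups given BATF (3591 and 4059); only the naive and day 3 tables share a scale.

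The naive comparison asks whether KO cells differ from WT cells before activation. Notch1 was 4.52-fold lower in KO cells (log2 fold change −2.18 ± 0.30 SE, adjusted p = 0.609 in limma), with every KO library below every WT library, and Dtx1 differed in the same way (−1.87 ± 0.32). Ifit1 and Isg15, genes induced by interferon, were at 2066 ± 442 and 1151 ± 273 in WT and at 975 ± 105 and 526 ± 41.3 in KO cells. None of the 11765 genes tested passed in limma and 279 had an unadjusted p under 0.05. On the recovered reads edgeR passed 0 genes and DESeq2 passed 7. The authors' deposited table has 6 genes with an adjusted p under 0.05, Notch1 among them at 1.30e-10 and Dtx1 at 6.17e-04. In 8.47% of the genes tested the 2 groups did not overlap, where chance gives 10.0% for 3 against 3 samples.

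As a group, the 36 measured interferon-stimulated genes were lower in naive KO cells by the set test (median log2 fold change −0.45, 2 of 36 above 0, adjusted p = 7.91e-25). That call was lost at adjusted p = 0.296 with an estimated correlation. Of these genes 0 passed in limma over all genes tested and 3 fell adjusted over the list alone. The 7 mitochondrially encoded transcripts were lower too (median −0.61, adjusted p = 6.20e-10; adjusted p = 0.296 with an estimated correlation). Of these 6 fell adjusted over the list alone, among them mt-Nd5 at 39338 ± 4909 in WT and 23762 ± 6749 in KO cells. Mitochondrial transcripts took 2.97% ± 0.291 of the reads in naive WT and 1.99% ± 0.316 in naive KO libraries (SD, n = 3 each). Ribosomal protein genes (median −0.21, adjusted p = 1.36e-04) and genes of oxidative phosphorylation (median −0.08, adjusted p = 0.026) were also lower. These had adjusted p = 0.571 and adjusted p = 0.661 with an estimated correlation. Genes of the IL-2 and STAT5 pathway were higher (median 0.20, adjusted p = 0.00521; adjusted p = 0.296 with an estimated correlation). In these 3 lists 0 members passed in limma, over all genes or adjusted over the list alone. Leaving out 1 library moved them. The oxidative phosphorylation call was lost without WT replicate 2 (median 0.03, adjusted p = 0.89), KO replicate 2 (−0.06, adjusted p = 0.275) or KO replicate 3 (−0.00862). Its median was −0.16, −0.18 and −0.23 without WT replicate 1, WT replicate 3 and KO replicate 1. The ribosomal protein call was lost without WT replicate 2 (−0.11, adjusted p = 0.0787) or KO replicate 2 (−0.14, adjusted p = 0.0658), and its median was −0.33 and −0.41 without WT replicate 3 and KO replicate 1. The IL-2 and STAT5 call was lost without WT replicate 3 (0.13, adjusted p = 0.185) or KO replicate 1 (0.19, adjusted p = 0.231), and its median was 0.32 without WT replicate 1. The interferon median was −0.25 without WT replicate 1. Rgs1 (2840 ± 550 in WT, 1606 ± 637 in KO) and Cd160 (318 ± 54.3 and 156 ± 26.3) had the smallest p of the tissue-residency and inhibitory-receptor lists without passing. The B cell and apoptosis lists, neither of them called, had a median and mean above 0 and a test that pointed down.

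On day 3 of infection the comparison asks what loss of the receptors does in responding cells. Of the Notch target genes, Dtx1 fell from 1622 ± 441 to 206 ± 82.4 (8.17-fold, log2 fold change −3.03 ± 0.22 SE, adjusted p = 3.11e-08, n = 8 each). Hes1 fell from 84.0 ± 37.8 to 19.4 ± 13.3 (−2.15 ± 0.31) and Nrarp from 25.6 ± 12.9 to 9.37 ± 3.99 (−1.29 ± 0.30). These are all 3 measured members of the list of Notch targets, too few for a set test. Il2ra, the alpha chain of the IL-2 receptor, fell 2.78-fold from 13729 ± 2053 to 4956 ± 890.0, and Klf2, a transcription factor that drives S1pr1, fell 3.64-fold. Tcf7 (the transcription factor TCF-1, 2.38-fold), Ly6c2 (2.99-fold) and the integrin gene Itgb1 (3.26-fold, from 3129 ± 442 to 10366 ± 2496) rose in KO cells.

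Of 11337 genes tested, 828 passed in limma, 458 higher and 370 lower in KO, and 147 of them differed at least 2-fold (71 higher and 76 lower). The lower genes with the largest change and no overlap between the groups included Cd22, a lectin that restrains B cell receptor signalling (481 ± 112 to 73.6 ± 34.3), and Gcnt1, which builds branched O-glycans (384 ± 90.8 to 65.4 ± 16.3). Tubb3, Maats1 and Trib2 were others (log2 fold changes −2.37, −2.05 and −1.75). The higher ones included Ms4a4c (156 ± 24.9 to 665 ± 92.8) and Dapl1 (100.8 ± 13.1 to 430 ± 59.9). Capn3, Samd3, Tuba8 and Hc were others (log2 fold changes 2.10, 2.09, 1.92 and 1.96). Batf, at 1731 ± 272 in WT and 1366 ± 198 in KO cells, did not pass in limma (−0.34 ± 0.11, adjusted p = 0.0556), nor did Notch2 (−0.32 ± 0.15, adjusted p = 0.227). For Batf the adjusted p was 0.0318 in DESeq2 on the recovered reads and 0.0444 in the authors' deposited table, where 860 genes are under 0.05 (456 higher and 404 lower). In 2.06% of the genes tested the groups did not overlap, where chance gives 0.0155% for 8 against 8. Leaving out each library in turn gave 632 to 1402 genes, the latter without day 3 KO replicate 7. On the recovered reads DESeq2 passed 1101 genes and edgeR 838.

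Of 28 measured naive and memory genes 12 rose on day 3, among them Tcf7, Ly6c2 and Dapl1, 4 fell, Klf2 among them, and 12 did not pass. Of these 13 rose and 5 fell adjusted over the list alone. Their set test pointed up (median log2 fold change 0.06, mean 0.27, adjusted p = 0.00164; adjusted p = 0.42 with an estimated correlation). The median was 0.02 without WT replicate 3 or KO replicate 7, 0.11 without KO replicate 2 and 0.14 without KO replicate 5. Of 35 measured effector genes 5 rose, including the receptors Cxcr3 (2.07-fold), Klrd1 (2.40-fold) and Klrk1 (1.71-fold). Another 9 fell, including Prdm1, the gene of the repressor Blimp-1 (693 ± 82.7 to 302 ± 49.3), and the list was not called (adjusted p = 0.124). Havcr2 (TIM-3), Tigit and Nt5e (CD73) fell among 15 measured inhibitory-receptor genes (log2 fold changes −1.25, −1.12 and −2.25), where 1 rose. Among 25 genes of T cell receptor activation 4 fell, including Il2ra, Icos (−0.72) and Tnfrsf9 (−0.83), and 1 rose. Of 19 residency genes 6 rose, including Itgb1 and Zfp683, which encodes Hobit (25.1 ± 7.89 to 87.4 ± 28.2), and 5 fell. None of these last 3 lists was called.

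Of 37 interferon-stimulated genes 7 rose on day 3, among them Ifi27l2a (649 ± 224 to 1183 ± 163), Slfn1, Isg20 and Usp18 (log2 fold changes 0.92, 0.84 and 0.58). None fell, and 19 rose adjusted over the list alone. Their set test pointed up (median 0.39, adjusted p = 3.46e-08; adjusted p = 0.42 with an estimated correlation). Of 20 genes of amino acid uptake and synthesis, many of them targets of ATF4, 2 fell, Asns (1565 ± 337 to 1012 ± 278) and Mthfd2 (4280 ± 387 to 3394 ± 331). In all 12 fell adjusted over the list alone (median −0.32, adjusted p = 1.81e-04; adjusted p = 0.42 with an estimated correlation). Ribosomal protein genes (median 0.17, adjusted p = 6.28e-04, 0 passed) and oxidative phosphorylation genes (median 0.11, adjusted p = 0.00883, 1 rose) shifted up, with adjusted p = 0.777 for both with an estimated correlation. In limma 0 passed in either list adjusted over the list alone. Among 24 IL-2 and STAT5 genes 4 rose and 4 fell, Il10 (97.3 ± 28.2 to 31.2 ± 9.14) among the latter. The residency, IL-2 and STAT5, mitotic and apoptosis lists had medians below 0 and tests that pointed up, none was called, and the IL-2 and STAT5 and mitotic medians lay above 0 with quantile normalization.

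Markers of other cell types were read beside these groups. Of 14 B cell genes Cd22 fell and Ighm, the immunoglobulin mu chain, rose (895 ± 281 to 3040 ± 629, log2 fold change 1.80 ± 0.17). Cd74 (208 and 266), Igkc (109 and 182), Cd79b (95.6 and 81.6), H2-Eb1 and H2-Aa did not pass. Of 7 myeloid genes 2 fell, Hmox1 (321 ± 26.9 to 211 ± 41.4) and Itgax (460 ± 103 to 223 ± 53.0). In all 3 fell adjusted over the list alone (median −0.52, adjusted p = 0.0294; adjusted p = 0.565 with an estimated correlation). That call was lost without WT replicate 2, 3, 4 or 6 (medians −0.37, −0.40, −0.17 and −0.41, adjusted p = 0.0536, 0.0654, 0.0841 and 0.0888) or KO replicate 6, 7 or 8 (−0.35, −0.21 and −0.49, adjusted p = 0.188, 0.238 and 0.0728).

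The co-culture asks the converse question, what a Notch ligand adds to activated cells. Dtx1 rose 11.7-fold on DLL4 feeders, from 43.6 ± 21.9 to 573 ± 329 normalized counts (log2 fold change 3.55 ± 0.47 SE, adjusted p = 0.0474 in limma, n = 3 each). Ifi27l2a, an interferon-stimulated gene, rose 2.42-fold from 1052 ± 116 to 2625 ± 866 (1.27 ± 0.18, adjusted p = 0.0474). Of 11638 genes tested these 2 alone passed in limma, with 1154 at an unadjusted p under 0.05. On the recovered reads edgeR passed 0 genes and DESeq2 81, and the authors' deposited table has 58 with an adjusted p under 0.05. The mean column of that table is not the mean of its 6 libraries, so which libraries entered that fit is not known. Gzmb (granzyme B, 1382 ± 813 and 3891 ± 763), Il2ra (839 ± 281 and 1572 ± 175), Nt5e (38.5 ± 14.7 and 128 ± 15.5) and Slamf6 (770 ± 77.2 and 1250 ± 165) were higher without passing. Zfp683 (177 ± 9.55 and 54.3 ± 28.9) and Id3 (572 ± 48.9 and 297 ± 73.4) were lower without passing, and these 6 genes had adjusted p values from 0.0829 to 0.0918. In 15.4% of genes the groups did not overlap, where chance gives 10.0%. The count rested on single libraries: 232 genes passed without OP9 replicate 1 (201 higher and 31 lower), 27 without OP9-DLL4 replicate 2, 1 without OP9-DLL4 replicate 1, and 0 without OP9 replicate 2, OP9 replicate 3 or OP9-DLL4 replicate 3.

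Groups of genes moved together on DLL4. Of 36 interferon-stimulated genes 34 had a log2 fold change above 0, 1 rose over all genes and 26 rose adjusted over the list alone, among them Rsad2 (113 ± 20.3 and 537 ± 356) and Ifih1 (274 ± 54.7 and 568 ± 116). The set test pointed up (median 1.00, adjusted p = 7.49e-29; adjusted p = 0.426 with an estimated correlation), and the median was 0.64 without OP9-DLL4 replicate 1. Of 26 genes of glycolysis 25 lay above 0, and 19 rose adjusted over the list alone (median 0.82, adjusted p = 8.89e-14; adjusted p = 0.475 with an estimated correlation). Their median ran from 0.57 without OP9 replicate 2 to 1.24 without OP9 replicate 1. Examples were Pkm (13115 ± 7727 and 21974 ± 5052), Ldha (11241 ± 5077 and 17336 ± 3254), Pdk1 (3071 ± 1246 and 4768 ± 991) and Aldoc (1036 ± 917 and 2188 ± 792). In OP9 replicate 1 Aldoc stood at 2095 and Gzmb at 2314, against 483 and 817 in replicate 2 and 531 and 1014 in replicate 3. The G1/S list of replication genes (median −0.29, adjusted p = 6.37e-10; adjusted p = 0.475 with an estimated correlation) was lower, as were mitotic genes (median −0.21, adjusted p = 3.16e-05; adjusted p = 0.63 with an estimated correlation). The mitotic call was lost without OP9-DLL4 replicate 3, the library labelled as spleen (median −0.04, adjusted p = 0.452). The median was −0.09 without OP9 replicate 3 (adjusted p = 0.0266) and −0.34 without OP9-DLL4 replicate 2. Mcm2 stood at 836 ± 95.5 and 586 ± 118 and Mki67 at 6294 ± 892 and 4601 ± 353. In limma 0 replication genes and 1 mitotic gene fell adjusted over the list alone.

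Smaller shifts on DLL4 were upward for cholesterol synthesis (median 0.23, adjusted p = 4.76e-05, 2 higher adjusted over the list alone) and ribosomal protein genes (0.13, adjusted p = 7.73e-07, 0 in limma adjusted over the list alone), with adjusted p = 0.475 and adjusted p = 0.533 with an estimated correlation. Effector genes (median 0.07) and 5 myeloid genes (0.63) shifted up, both at adjusted p = 0.0219, with adjusted p = 0.63 and adjusted p = 0.426 with an estimated correlation. Of 28 effector genes 5 rose and 1 fell, and 1 myeloid gene rose, adjusted over the list alone. The effector call was lost without OP9 replicate 2 (median 0.02, adjusted p = 0.355), OP9 replicate 3 (0.03, adjusted p = 0.0778) or OP9-DLL4 replicate 2 (8.03e-04, adjusted p = 0.223), and the median was 0.16 without OP9 replicate 1. The myeloid call was lost without OP9-DLL4 replicate 2 (0.74, adjusted p = 0.0532), the median was 0.34 without OP9 replicate 1, and too few of its genes were measured for a test without OP9-DLL4 replicate 1 or 3. Amino acid genes shifted down (−0.23, adjusted p = 0.0012, 2 lower adjusted over the list alone; adjusted p = 0.426 with an estimated correlation), with a median of −0.14 without OP9 replicate 3. The 18 measured stromal genes, listed as markers of the feeder cells, were lower (median −0.44, adjusted p = 0.0331; adjusted p = 0.63 with an estimated correlation). Adjusted over the list alone 1 rose, Lgals3bp (1501 ± 158 and 2498 ± 757). It is not particular to feeder cells, since it stood at 5095 ± 2251 in naive WT cells, on the scale of that table. Fn1 stood at 352 ± 321 and 111 ± 56.6 and Sparc at 66.1 ± 42.0 and 30.2 ± 14.2. The stromal call was lost without OP9 replicate 3, where Fn1 stood at 716 (median 0.33, adjusted p = 0.278), or OP9-DLL4 replicate 1 (−0.09, adjusted p = 0.483). The median was −0.96, −0.94 and −0.68 without OP9 replicate 1, OP9 replicate 2 and OP9-DLL4 replicate 2. Medians and tests differed in sign for the dissociation-stress list, means and tests for the Notch pathway list, neither was called, and both medians changed sign under another scaling.

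**Figure D2:**
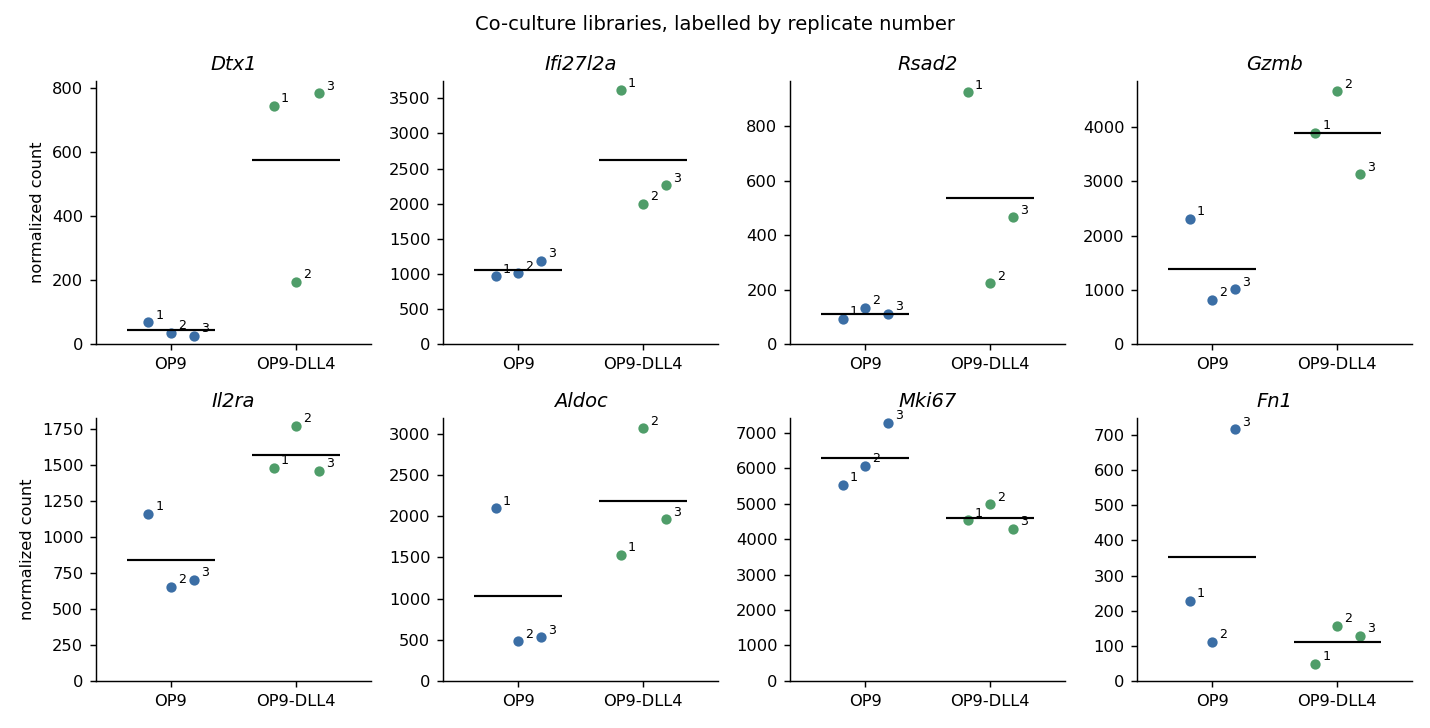
Normalized counts of 8 genes in the 6 co-culture libraries, 3 on OP9 and 3 on OP9-DLL4 feeders, each point labelled with its replicate number. Dtx1 lies between 26.3 and 68.3 on OP9 and between 195 and 782 on OP9-DLL4, and OP9 replicate 1 is apart from the other OP9 libraries in Gzmb (2314) and Aldoc (2095).

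In cells given the empty retrovirus, the comparison of KO with WT asks for the effect of genotype in transduced cells on day 3. Notch1 fell 4.63-fold (log2 fold change −2.21 ± 0.05 SE), Dtx1 3.83-fold (1019 ± 119 to 264 ± 13.9) and Cd22 3.71-fold (979 ± 96.8 to 264 ± 29.8), with n = 4 each. Tex11, a meiosis gene, rose 13.7-fold (21.9 ± 3.35 to 309 ± 10.8). Zfp683 (20.1 ± 3.52 to 107 ± 19.9), Itgb1 (9019 ± 202 to 30227 ± 2043), Trat1 (4.18-fold, an adaptor of the T cell receptor) and Hc (6.97-fold) rose as well. Klf2 (2.18-fold), its target S1pr1 (1338 ± 153 to 669 ± 62.5), Klf3 (544 ± 66.0 to 205 ± 37.6), Il31ra and Cmklr1 (log2 fold changes −1.95 and −1.62) fell. Batf fell 1.18-fold (−0.24 ± 0.05, adjusted p = 0.00116) and Notch2 1.26-fold (−0.34 ± 0.05, adjusted p = 1.20e-05).

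Of 11690 genes tested, 1871 passed in limma, 886 higher and 985 lower in KO Empty, and 126 differed at least 2-fold (72 higher and 54 lower). In 18.9% of genes the groups did not overlap, where chance gives 2.86% for 4 against 4. Of 26 genes of T cell receptor activation 12 rose, among them Egr3, a transcription factor induced by receptor signals (23.9 ± 3.48 to 72.2 ± 13.8), and Xcl1, a chemokine (453 ± 22.0 to 1217 ± 181). Another 3 fell, Il2ra (1.52-fold) and Tnfrsf9 (1.61-fold) among them. The set test pointed up (median 0.22, adjusted p = 7.40e-05) and kept its call with an estimated correlation (adjusted p = 0.0343); 13 were higher and 3 lower adjusted over the list alone. Of 19 genes of AP-1 and related bZIP factors 7 rose, Atf3 (80.8 ± 13.3 to 160 ± 25.1) and Junb (3988 ± 104 to 5500 ± 629) among them, and 2 fell. Adjusted over the list alone 9 rose and 3 fell (median 0.24, adjusted p = 0.00646; adjusted p = 0.251 with an estimated correlation), and the median was 0.15 without KO Empty replicate 4. Both are also in the list of genes that respond to cell dissociation. Of its 18 members 7 rose and none fell, with 10 higher adjusted over the list alone (median 0.25, adjusted p = 4.41e-05; adjusted p = 0.0759 with an estimated correlation), with a median of 0.16 without KO Empty replicate 4.

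Replication and mitotic genes were lower in KO Empty by small amounts. Of 35 G1/S genes 11 fell, including Rrm2 (11094 ± 232 to 9366 ± 220) and E2f8 (2345 ± 114 to 1932 ± 58.7), and 18 adjusted over the list alone (median −0.08, adjusted p = 2.53e-06; adjusted p = 0.0638 with an estimated correlation). Of 35 mitotic genes 8 fell, including Nek2 (2950 ± 139 to 2376 ± 43.3) and the kinesin gene Kif11 (1.11-fold), and 8 adjusted over the list alone (median −0.08, adjusted p = 9.95e-05; adjusted p = 0.11 with an estimated correlation). Of 24 IL-2 and STAT5 genes 9 rose and 4 fell, the counts also adjusted over the list alone (median 0.12, adjusted p = 0.0228; adjusted p = 0.212 with an estimated correlation), a call lost without KO Empty replicate 2 (median 0.07, adjusted p = 0.0621). Of 32 oxidative phosphorylation genes 6 rose, 8 adjusted over the list alone (median 0.06, adjusted p = 0.00246). Of 32 ribosomal protein genes 5 rose, also adjusted over the list alone (median 0.07, adjusted p = 4.41e-05), and both lists had adjusted p = 0.674 with an estimated correlation. The interferon, amino acid and naive and memory lists, all called on day 3, were not called here (medians 0.07, −0.05 and 0.08). Effector genes went both ways, 9 rising and 13 falling of 35 (median 0.04, mean −0.06, test pointing down, adjusted p = 0.951). Among inhibitory receptors Havcr2 (1.78-fold) and Nt5e (154 ± 27.6 to 60.6 ± 11.0) fell and Nrp1 (215 ± 28.3 to 516 ± 39.3) rose. Rbpj, the transcription factor that Notch receptors act through, rose from 1158 ± 75.2 to 1802 ± 63.9, Ly6c2 rose 1.99-fold and Ighm 1.88-fold. The ribosome-biogenesis and apoptosis lists had medians below 0 and means and tests above 0, and the B cell list a median and test above 0 and a mean below 0, none of them called. With quantile normalization the first 2 medians lay above 0.

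The genotype effects in transduced cells and on day 3 come from separate libraries. Among 10855 genes tested in both, 256 were higher in KO in both (34.8 would be shared by chance, Fisher's exact test, adjusted p = 6.32e-175). In both 224 were lower (31.1 by chance, adjusted p = 1.24e-151), while 3 and 2 passed in opposite directions (28.1 and 38.5 by chance). The log2 fold changes correlated across genes (Pearson's r = 0.624, Spearman's rho = 0.543), and genes are not independent replicates. Sets drawn from the day 3 comparison by a fixed rule moved the same way. Of the 201 genes higher there 188 were tested and had a median of 0.54 in KO Empty against WT Empty. Of the 209 lower 198 were tested, with a median of −0.60. Both calls held with an estimated correlation (adjusted p = 1.58e-04 each). Naive and day 3 fold changes had r = −0.129 and rho = −0.223 over 10491 genes, and neither day 3 set was called in naive cells (medians −0.00113 and 0.04, adjusted p = 0.594 and 0.238). With sets drawn by a stricter rule (adjusted p under 0.01 and 2-fold) the lower set was called there, downward (35 tested, median −0.11, adjusted p = 0.00124; adjusted p = 0.0715 with an estimated correlation).

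**Figure D3:**
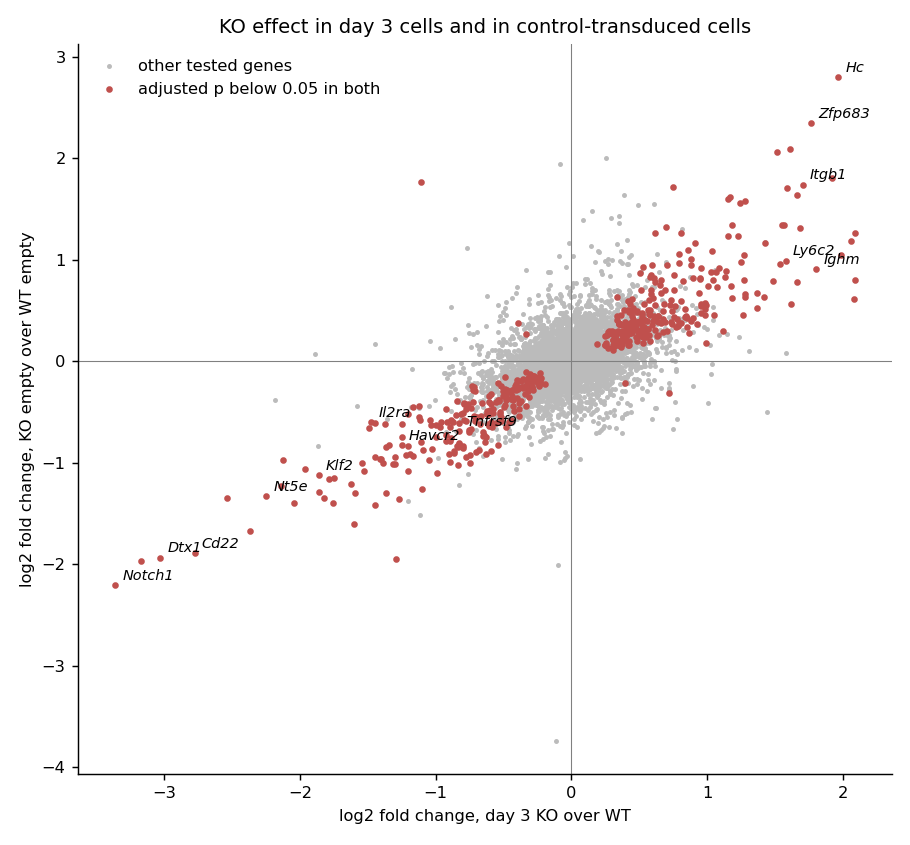
Log2 fold change of KO against WT on day 3 (horizontal axis) and of KO Empty against WT Empty (vertical axis) for the genes tested in both; each point is 1 gene, and red points passed in both comparisons. Red points lie almost all in the quadrants where both changes have the same sign, 256 higher and 224 lower in both against 3 and 2 of opposite sign.

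In the co-culture the genes lower in day 3 KO cells were higher on DLL4 (147 tested, median 0.28, 106 above 0 and 41 below, adjusted p = 4.43e-11; adjusted p = 0.0636 with an estimated correlation). The genes higher in day 3 KO did not shift there (median −0.02, adjusted p = 0.611). With sets drawn by a stricter rule (adjusted p under 0.01 and 2-fold) both were called. The lower set had a median of 0.53 (42 tested, adjusted p = 2.64e-15; adjusted p = 0.0193 with an estimated correlation) and the higher set of −0.16 (59 tested, adjusted p = 0.00253; adjusted p = 0.0415 with an estimated correlation). The fold changes of the 2 comparisons had r = −0.0207 and rho = 0.0814 over 10530 genes. Of the 2 genes that passed on DLL4, Dtx1 was lower and Ifi27l2a higher in day 3 KO cells.

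Giving BATF to WT cells asks what added BATF does where Notch1 and Notch2 are present. Batf rose 3.51-fold (log2 fold change 1.81 ± 0.05 SE). Mmp10, a matrix metalloproteinase (62.0 ± 9.55 to 204 ± 19.9), the cadherin gene Cdh17 (204 ± 13.0 to 483 ± 25.9), Cd7 (73.2 ± 11.5 to 168 ± 25.9) and Hlf (2.01-fold) rose as well. Tns1 (218 ± 11.1 to 65.3 ± 15.5), Nebl, Pak6 and Adam8 fell (log2 fold changes −1.58, −1.24 and −1.12 for the last 3), as did Il10 (99.8 ± 9.35 to 42.8 ± 7.53), Gzmb (25916 ± 1512 to 17083 ± 1689) and the chemokine gene Ccl4 (124 ± 27.4 to 61.7 ± 11.2). Dtx1 and Cd22 fell (log2 fold changes −0.58 and −0.85), whereas Hey1, another Notch target, rose from 12.4 ± 4.49 to 29.5 ± 4.03. Of 11690 genes 703 passed in limma, 277 higher and 426 lower, and 42 differed at least 2-fold (24 and 18). Leaving out each of the 16 transduction libraries in turn gave 370 to 1008 genes, the latter without KO Batf replicate 4. Without both KO Batf replicate 4 and KO Empty replicate 3 there were 1234, and limma without trend gave 417. The count was 463 without WT Empty replicate 2, 396 without WT Empty replicate 4, 402 without WT Batf replicate 2 and 370 without WT Batf replicate 4. The groups did not overlap in 14.3% of genes, where chance gives 2.86%.

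Of 36 interferon-stimulated genes 12 fell in WT Batf, including Oas3 (875 ± 31.0 to 629 ± 57.4), Trim30a (1456 ± 132 to 1062 ± 35.0) and Ifi209 (1152 ± 78.9 to 785 ± 83.2), and none rose, with 15 lower adjusted over the list alone. Of 35 mitotic genes 13 fell, by small amounts (Kif20a 1.13-fold, Cenpf 1.29-fold), and 28 adjusted over the list alone. These set calls (median −0.35, adjusted p = 1.44e-11, and median −0.13, adjusted p = 6.47e-15) held with an estimated correlation, at adjusted p = 0.0309 and adjusted p = 0.00505. Of 35 effector genes 13 fell and 3 rose, Batf being 1 of these (5 higher and 16 lower adjusted over the list alone; median −0.18, adjusted p = 1.13e-04; adjusted p = 0.367 with an estimated correlation). Ribosome biogenesis shifted up (3 of 32 rose, 7 adjusted over the list alone; adjusted p = 1.21e-07), and residency genes down (2 rose and 4 fell of 20, with 2 and 8 adjusted over the list alone; adjusted p = 0.00273). Amino acid genes shifted up (1 of 18 rose; adjusted p = 0.0127) and G1/S genes down (2 of 35 fell; adjusted p = 0.04). The counts of the last 2 lists were the same adjusted over the list alone. AP-1 and related factors include the introduced Batf, and without it the list was not called (18 genes, 1 rose and 1 fell, median 0.07, adjusted p = 0.249). The effector call held without Batf (adjusted p = 8.40e-07). The amino acid call (median 0.07) was lost without WT Empty replicate 2 (0.06, adjusted p = 0.0779) or WT Batf replicate 1 (0.05, adjusted p = 0.14), and its median was 0.12 without WT Batf replicate 4. The G1/S call was lost without WT Empty replicate 2 or 4, WT Batf replicate 2 or 4, or KO Batf replicate 4 (adjusted p = 0.0779, 0.0927, 0.134, 0.0722 and 0.0535). The ribosome-biogenesis, residency, amino acid and G1/S lists each had adjusted p = 0.367 with an estimated correlation. IL-2 and STAT5 genes (1 rose and 4 fell of 24, also adjusted over the list alone; adjusted p = 0.0044) and B cell genes (2 of 9 fell, 4 adjusted over the list alone; adjusted p = 1.53e-04) shifted down, with adjusted p = 0.114 and adjusted p = 0.0805 with an estimated correlation. Median, mean and test differed in sign for the T cell receptor activation, apoptosis and mitochondrial lists, none of them called, and the mitochondrial median changed sign under another scaling.

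In KO cells the same addition raised Batf 4.67-fold (log2 fold change 2.22 ± 0.05 SE). Tmem255a (9.11 ± 5.83 to 55.8 ± 11.0), Cdh17 (105 ± 15.0 to 375 ± 32.9), Cd7 (3.62-fold) and Mmp10 (3.85-fold) rose. So did Stk32c (54.3 ± 11.0 to 180 ± 42.1) and the Notch target Dtx4 (21.5 ± 2.40 to 71.5 ± 7.86). Granzyme A (Gzma, 3528 ± 760 to 1400 ± 490), Adam8 (2.51-fold) and Ccl4 (121 ± 15.5 to 52.8 ± 4.32) fell, as did Ly6c2 (12895 ± 694 to 8193 ± 1210), Cd22 (2.06-fold) and Dtx1 (264 ± 13.9 to 134 ± 15.1). Notch1 itself fell 1.23-fold, and Notch2 did not pass (−0.11 ± 0.05, adjusted p = 0.116). In limma 1498 of 11690 genes passed, 712 higher and 786 lower, 75 of them at least 2-fold (33 and 42), and 953 passed without KO Empty replicate 2. The groups did not overlap in 14.9% of genes, where chance gives 2.86%.

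Interferon-stimulated genes had the smallest set test p of the lists in this comparison. Of 36, 24 fell and none rose, with 27 lower adjusted over the list alone, among them Ifi27l2a (650 ± 71.4 to 299 ± 54.0) and Ifi209 (1.93-fold). Of 35 mitotic genes 17 fell, 21 adjusted over the list alone, with Kif11 1.18-fold and Top2a 1.13-fold lower. Of 9 B cell genes 3 fell, 4 adjusted over the list alone. These calls (medians −0.54, −0.13 and −0.53, adjusted p = 2.60e-20, 4.73e-12 and 2.00e-05) held with an estimated correlation, at adjusted p = 0.00628, 0.00728 and 0.0442. Of 32 genes of ribosome biogenesis 19 rose and none fell, with 26 higher adjusted over the list alone, such as Nolc1 (8964 ± 486 to 10584 ± 419) and Rrp12 (1.19-fold; median 0.15, adjusted p = 2.19e-14; adjusted p = 0.266 with an estimated correlation). Of 18 amino acid genes 6 rose, 10 adjusted over the list alone, including Asns (599 ± 107 to 933 ± 306) and the transporter gene Slc7a5 (1.16-fold; median 0.14, adjusted p = 1.09e-05; adjusted p = 0.139 with an estimated correlation).

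Other lists were called in KO Batf against KO Empty with the preset correlation alone. Effector genes shifted down (7 rose and 16 fell of 35, 7 and 19 adjusted over the list alone; adjusted p = 1.36e-04). Naive and memory genes did too (4 rose and 11 fell of 28, 6 and 13 adjusted over the list alone; adjusted p = 0.00618). Both lists were at adjusted p = 0.401 with an estimated correlation. The effector list includes Batf, and its call held without it (adjusted p = 2.68e-06). AP-1 and related factors were not called without Batf (18 genes, 2 rose, median 0.05, adjusted p = 0.246). Myeloid genes (3 of 8 fell, 6 adjusted over the list alone; adjusted p = 0.00319) and ribosomal protein genes (1 of 32 fell, 0 adjusted over the list alone; adjusted p = 0.0402) shifted down, with adjusted p = 0.358 and adjusted p = 0.711 with an estimated correlation. The ribosomal protein call (median −0.03) was lost without KO Empty replicate 3 or 4 (−0.01 and −0.03, adjusted p = 0.435 and 0.0619) or KO Batf replicate 1 or 4 (−0.03 and −0.02, adjusted p = 0.0574 and 0.148). The T cell receptor activation list, which was not called, had a mean above 0 and a median and test below 0, and the median lay above 0 under both other scalings.

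**Figure D4:**
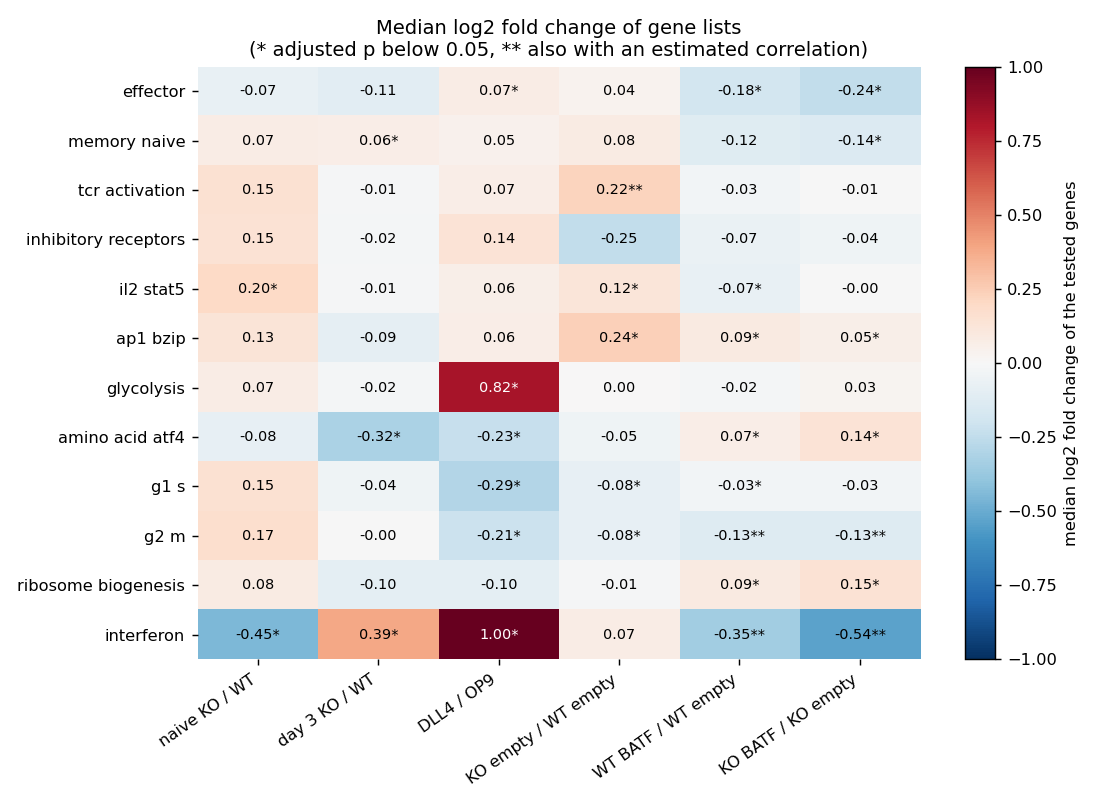
Median log2 fold change of 12 gene lists (vertical axis) in 6 comparisons (horizontal axis), as colour and as printed value; 1 star marks an adjusted p under 0.05 with the preset correlation and 2 stars a call that also held with an estimated correlation. Interferon-stimulated genes are lower in naive KO (−0.45), higher in day 3 KO (0.39) and higher on DLL4 (1.00), calls that were lost with an estimated correlation. They were not called in KO Empty against WT Empty (median 0.07) and are lower with BATF in WT (−0.35) and in KO cells (−0.54). The AP-1 list includes Batf and was not called without it in WT Batf against WT Empty or KO Batf against KO Empty (adjusted p = 0.249 and 0.246).

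How far KO cells with BATF differ from WT Empty was compared next. Tex11 rose 13.6-fold, Trat1 7.58-fold (73.5 ± 6.28 to 563 ± 32.4), Il21 4.65-fold (29.6 ± 2.13 to 142 ± 21.5) and Itgb1 3.48-fold. Cd22 fell 7.62-fold, Dtx1 7.56-fold, Gzma 6.10-fold (8101 ± 1376 to 1400 ± 490), Klf3 4.32-fold and Nt5e 4.02-fold. In limma 3499 genes passed, 1682 higher and 1817 lower, and 318 differed at least 2-fold (137 and 181). The groups did not overlap in 27.4% of genes, where chance gives 2.86%. Of 35 mitotic genes 31 fell, 33 adjusted over the list alone (median −0.21, adjusted p = 2.04e-14), a call that held with an estimated correlation (adjusted p = 0.00585). Interferon-stimulated genes (26 of 36 fell and 2 rose; adjusted p = 3.29e-09), G1/S genes (18 of 35 fell; adjusted p = 1.11e-05) and AP-1 and related factors (10 of 19 rose; adjusted p = 2.13e-05) each had adjusted p = 0.0646 with an estimated correlation. Adjusted over the list alone, 27 fell and 2 rose, 20 fell and 1 rose, and 10 rose in these 3 lists. Without the introduced Batf 9 of 18 AP-1 and related factors rose (adjusted p = 4.82e-04; adjusted p = 0.139 with an estimated correlation). T cell receptor activation genes (15 rose and 5 fell of 26, 16 and 5 adjusted over the list alone; adjusted p = 0.00816) and dissociation-stress genes (11 of 18 rose, also adjusted over the list alone; adjusted p = 1.84e-04) shifted up, both with adjusted p = 0.0685 with an estimated correlation. Ribosome biogenesis shifted up (21 of 32 rose, also adjusted over the list alone; adjusted p = 1.53e-08; adjusted p = 0.352 with an estimated correlation). Effector genes shifted down (10 rose and 18 fell of 35, 10 and 19 adjusted over the list alone; adjusted p = 0.0318) and so did myeloid genes (5 of 8 fell, also adjusted over the list alone; adjusted p = 0.00132). These had adjusted p = 0.626 and adjusted p = 0.245 with an estimated correlation. The effector call was lost without WT Empty replicate 4 (adjusted p = 0.0525) and held without Batf, which is in that list too (adjusted p = 0.00466). For the residency and cholesterol lists, neither called, the mean differed in sign from the median and test.

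Whether BATF acted differently in the 2 genotypes was tested by the interaction, which passed for 12 of 11690 genes in limma, with 959 at an unadjusted p under 0.05. The log2 effect of BATF was larger in KO cells for Il21, a cytokine gene (WT Empty 29.6 ± 2.13, WT Batf 20.7 ± 3.44, KO Empty 85.0 ± 9.60, KO Batf 142 ± 21.5; difference 1.24 ± 0.21 SE, adjusted p = 0.016). The same held for Rgs16 (249 ± 21.8, 291 ± 18.5, 454 ± 73.5 and 1117 ± 344 in the same order; 1.03 ± 0.21), Stk32c and Rai14 (1.15 ± 0.22 and 0.79 ± 0.13). It was more negative in KO cells for Il10ra (648 ± 35.6, 418 ± 23.6, 906 ± 106 and 403 ± 17.2; −0.53 ± 0.10). So it was for Ifi27l2a (−0.72 ± 0.13), St3gal6 (−0.57 ± 0.11), Mpp1 (−0.38 ± 0.07) and Dpp4 (−0.28 ± 0.05). Batf itself differed by 0.41 ± 0.07 (adjusted p = 0.016), at 3591 in WT Batf and 4059 in KO Batf. For these genes, and for the lists and sets below, a response that depends on genotype cannot be told apart from the larger rise of Batf in KO cells. Notch1 and Notch2 did not pass (−0.23 ± 0.07 and −0.03 ± 0.06). DESeq2 passed 31 genes, edgeR 11 and limma without trend 2, and leaving out both KO Batf replicate 4 and KO Empty replicate 3 gave 43. Of 100 splits of the libraries 4 gave at least 12 genes, the real one included, and the highest gave 118. That share is under 0.05, but such a count is not unique to the real groups. The number moved with single libraries, to 35 without KO Batf replicate 4, 20 without KO Empty replicate 3, 4 without WT Batf replicate 3 and 5 without WT Empty replicate 3 or WT Batf replicate 4. It was 6 without WT Empty replicate 1 or 2, KO Empty replicate 1 or KO Batf replicate 2, and 7 without WT Batf replicate 1 or 2.

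For lists, interferon-stimulated genes responded to BATF more negatively in KO than in WT cells (median difference −0.19, 1 of 36 passed and 9 lower adjusted over the list alone, adjusted p = 4.79e-08; adjusted p = 0.182 with an estimated correlation). Ribosome biogenesis differed upward (median 0.07, adjusted p = 4.49e-04; adjusted p = 0.673 with an estimated correlation). Glycolysis and amino acid genes differed upward (medians 0.04 and 0.07, adjusted p = 0.0146 each) and mitochondrially encoded and myeloid genes downward (medians −0.06 and −0.35, adjusted p = 0.0254 and 0.0298), all at adjusted p = 0.61 with an estimated correlation. In limma 0 members of these last 5 lists passed, over all genes or adjusted over the list alone. Each of the 5 calls was lost without some library. Ribosome biogenesis was at adjusted p = 0.22 without KO Batf replicate 4 (median 0.03) and glycolysis at adjusted p = 0.0535 without WT Batf replicate 4. Amino acid genes were at adjusted p = 0.0739, 0.0535 and 0.0748 without WT Batf replicate 3, WT Batf replicate 4 and KO Batf replicate 3. Mitochondrially encoded genes lost the call without WT Empty replicate 2 or 4, WT Batf replicate 2 or 4, KO Empty replicate 1 or KO Batf replicate 3 (adjusted p = 0.135, 0.0635, 0.074, 0.0508, 0.265 and 0.0748). Myeloid genes lost it without WT Empty replicate 4, WT Batf replicate 3 or 4, KO Empty replicate 2 or 4, or KO Batf replicate 4 (adjusted p = 0.0635, 0.0772, 0.0508, 0.114, 0.0786 and 0.242). Medians moved as well: ribosome biogenesis to 0.04 without WT Empty replicate 3, glycolysis to 0.03 without KO Empty replicate 2 and amino acid genes to 0.10 without WT Batf replicate 1. The mitochondrially encoded median was −0.12, −0.11, −0.03 and −0.12 without WT Empty replicate 3, KO Empty replicate 2, KO Empty replicate 1 and KO Batf replicate 4, and the myeloid median −0.22 without KO Batf replicate 4. Signs differed between median, mean and test for the AP-1, mitotic and dissociation-stress lists, none of them called.

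BATF was set against the genotype effect in the same libraries. Of the genes higher in KO Empty than in WT Empty, 155 were lower and 58 higher in KO Batf than in KO Empty (59.6 and 54.0 for independent lists), and of those lower in KO Empty, 97 were higher and 184 lower (59.99 and 66.2). The comparisons share the KO Empty libraries, so in 20 simulations with unchanged groups their fold changes had r = −0.498 and shared 0 calls. With no change simulated few genes could pass, so these 0 calls do not show how far shared libraries alter an overlap. The observed r across genes was −0.015, and the covariance of −0.00101 lay above the simulated −0.00887 by 0.00786. When the KO Empty libraries were divided between the comparisons, in 6 ways, r averaged 0.109 (0.06 to 0.174). Then 55 to 71 genes were higher then lower and 33 to 39 lower then higher, with 24 to 50 higher and 40 to 210 lower in both. For BATF in WT cells, which shares WT Empty, 71 genes were higher and 137 lower in both comparisons (21.0 and 35.9 for independent lists). Higher in KO Empty and lower in WT Batf were 70, and the reverse 27 (32.3 and 23.3). There r was 0.306 against a simulated 0.494, the covariance of 0.0174 exceeded the simulated 0.0088 by 0.00862, and r with divided controls was 0.123 (0.0954 to 0.171). With divided controls 18 to 24 genes were higher and 24 to 52 lower in both, and 12 to 37 and 11 to 22 went opposite ways. No number expected by chance was computed for the counts with divided controls.

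The day 3 sets were followed through BATF as well. The genes higher in day 3 KO cells had a median of −0.16 in KO Batf against KO Empty (51 of 188 fell and 9 rose, adjusted p = 1.34e-07; adjusted p = 0.0801 with an estimated correlation) and of −0.10 in WT Batf against WT Empty (adjusted p = 0.00142; adjusted p = 0.292 with an estimated correlation). Their interaction was −0.10 (adjusted p = 1.34e-04; adjusted p = 0.21 with an estimated correlation). The genes lower in day 3 KO cells did not shift back in KO Batf (median −0.06, 32 rose and 48 fell of 198, adjusted p = 0.238). The stricter lower set was called further down there (median −0.23, 7 rose and 24 fell of 61, adjusted p = 7.32e-04; adjusted p = 0.185 with an estimated correlation). The lower genes had a median of −0.12 in WT Batf (adjusted p = 0.0101; adjusted p = 0.405 with an estimated correlation) and of 0.01 for the interaction (adjusted p = 0.256; −0.04 with the stricter set, adjusted p = 0.874). Against WT Empty, KO Batf cells still had medians of 0.37 for the higher and −0.62 for the lower set, both calls holding with an estimated correlation (adjusted p = 0.0191 and 0.00116).

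**Figure D5:**
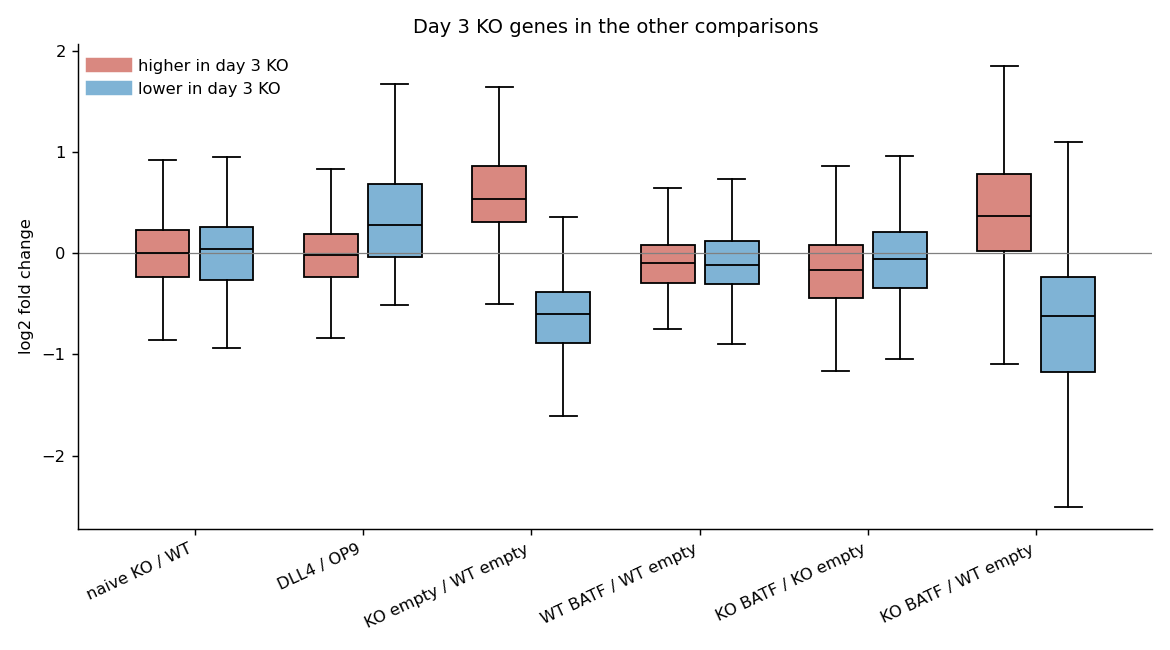
Log2 fold changes (vertical axis) of the genes higher and of the genes lower in day 3 KO cells, in 6 other comparisons (horizontal axis); boxes show the median and quartiles, and whiskers reach to 1.5 times the interquartile range, with points beyond them not drawn. The sets lie apart in KO Empty against WT Empty (medians 0.54 and −0.60) and in KO Batf against WT Empty (0.37 and −0.62).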

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

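The test of genes near Notch1 and Notch2 was chosen before its result was seen, and the tests of B cells, of the co-culture and of the difference between day 3 and naive cells were chosen after.

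Single libraries lay apart from the rest of their group in 17 of 262 tests of a gene in a group by Dixon's test, where chance gives about 1 in 20 groups. The naive and co-culture groups, with 3 libraries each, were not tested in this way. On day 3, Notch1 was at 1932 normalized counts in WT replicate 6 (others 2648 to 3283), and Hes1 at 49.7 and Klf2 at 372 in KO replicate 5 (others 8.51 to 23.5 and 134 to 245). KO Empty replicate 3 had 4 such genes: Egr3 at 92.7 (others 62.8 to 67.8), S1pr1 at 577 (692 to 715), Junb at 4563 (5711 to 5878) and Cd7 at 50.7 (82.7 to 85.1). WT Empty replicate 2 had 3: Egr3 at 29.1 (22.0 to 22.3), Nek2 at 2743 (2999 to 3037) and Ifi209 at 1269.7 (1102 to 1121). Rrm2 stood at 10747 in WT Empty replicate 1 (11198 to 11232), E2f8 at 2174 in WT Empty replicate 3 (2395 to 2413) and at 1844.5 in KO Empty replicate 4 (1953 to 1974). In the groups given BATF, Cdh17 stood at 444 in WT replicate 3 (492 to 499.9), Notch1 at 389 and Klf3 at 164 in KO replicate 1 (434 to 442 and 110.2 to 117), and Gzma at 671 in KO replicate 4 (1587 to 1735).

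The effect of BATF differed between WT and KO cells by limma's interaction test for 12 genes. That count fell to 2 in limma without trend, and another split of the libraries gave 118. The log2 difference, KO minus WT, was upward for Rgs16 1.03, Il21 1.24, Stk32c 1.15, Rai14 0.79, Batf 0.41 and 1700017B05Rik 0.35. Ifi27l2a −0.72, St3gal6 −0.57, Il10ra −0.53, Mpp1 −0.38 and Dpp4 −0.28 differed downward. Since Batf rose further in KO cells, an effect of genotype cannot be told apart from one of the amount of Batf.

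The KO effect differed between day 3 and naive cells for 16 of the 36 named genes measured at both stages, in a fit of both tables chosen after seeing the data (log2 effect on day 3 minus naive). Most of these genes were named for their change in the same libraries, which favours such a difference. Over all genes measured at both stages 115 of 10491 passed. Upward were the interferon-stimulated Ifit1 1.81, Isg15 1.603, Isg20 1.63, Usp18 1.44, Ifi27l2a 1.38 and Slfn1 1.31. Naive, memory, residency, effector and inhibitory-receptor genes followed with Ly6c2 1.51, Dapl1 2.17, Itgb1 1.82, Zfp683 1.63, Klrd1 1.58 and Cd160 1.07. So did Ms4a4c 2.62 and Ighm 1.91. Downward were Tigit −1.92 and Trib2 −1.47. Genes with too few reads in naive cells for a KO effect there, such as Cd22, Gcnt1 and Havcr2, were left out.

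Cd22 fell and Ighm rose in day 3 KO cells, and both are in the list of B cell markers, of which 14 of 21 genes were tested on day 3 and 8 also in naive T cells. Fewer B cells in the KO sorts would lower the other markers with Cd22, but their median log2 fold change was 0.48, and more B cells would raise the 5 most abundant of the others about as far as Ighm (1.80), where the median was again 0.48 and 0 passed in limma. Cd74, the most abundant, stood at 208 in WT and 266 in KO, Igkc at 109 and 182, and Ighm at 895 and 3040. The sort for CD8, CD45.2 and CD44 selects against B cells, but the B cell markers were uneven between day 3 libraries. Their mean log2 count ran from 4.59 in WT replicate 7 to 7.39 in WT replicate 4, with 7.26 in KO replicate 5. In naive cells Ighm already stood at 11525 in WT and 10928 in KO with Cd74 at 40.4 and 66.9, and Cd22 at 0 and 0.274. A hypothesis that stays open is that the T cells carry these transcripts themselves, which was not tested.

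Interferon-stimulated genes were higher on DLL4 feeders, with a median log2 fold change of 1.00 over 36 genes. That call was lost with an estimated correlation, and Ifi27l2a alone of them passed over all genes tested. A single apart library, OP9 replicate 1, does not account for the shift, since the median was 0.88 without that library and ranged from 0.64 to 1.26 when each was left out. If Notch signals raised the same genes in infected cells, these genes would be lower in KO cells. On day 3 they were higher (median 0.39), a call lost with an estimated correlation. In KO Empty against WT Empty they were not called (median 0.07). Neither comparison shows the fall that this explanation needs, while naive KO cells had a median of −0.45. RNA of the feeder cells cannot be told apart from the effect. Of 32 stromal genes 18 were tested, against 4 on day 3, with a median of −0.44 (Fn1 352 without and 111 with DLL4). That median was 0.33 without OP9 replicate 3. The sort for CD8, CD45.2 and CD44 selects against feeder cells, but how many passed it was not measured. Whether the DLL4 feeders themselves differ in interferon production stays open.

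DNA of another mouse strain carried along with floxed alleles would place the KO calls near Notch1 and Notch2. Within 10 Mb of them 33 of 399 tested genes passed on day 3 (8.27%), against 794 of 10936 elsewhere (7.26%). The odds ratio was 1.15 (95% interval 0.775 to 1.66, Fisher's exact p = 0.433), and in KO Empty it was 1.00 (exact p = 1). No surplus of calls was thus seen near the 2 genes. With 399 tested genes in these regions, the test cannot speak to calls elsewhere. Single genes within the regions stay open. Among those named, Hc (from 34983331) and Nrarp (from 25180758) on chromosome 2 lie within 10 Mb of Notch1. Cd160 (chromosome 3, from 96798763) lies within 10 Mb of Notch2.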

How the results depend on the processing

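Of the alternatives named here, the fit of all 22 naive and day 3 libraries and the settings that leave out 2 libraries at once were chosen after seeing the data.

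Over all settings, results grouped as genes and lists stayed the same in 4335 cases and moved in 87. They became weaker in 257, stronger in 72 and reversed in 3. This group also holds the counts of genes called higher or lower. For a gene or list, the same means that direction and side of the threshold were kept. For a count it means only a limited change in size, and in this group moved applies to counts alone. Results grouped as counts and sets stayed the same in 176 cases and moved in 63. They became stronger in 5, weaker in 5 and reversed in 1. Depth limits genes with few reads, and the spread between libraries is a limit as well. Between replicates the mean chi-square, about 1 from counting error alone, was 1.86 to 8.63 in the transduction table, 5.36 to 82.1 on day 3, 10.2 to 24.9 in the co-culture and 28.6 to 88.1 in naive cells. The 2 limits were not compared for genes with few reads. For the changes below the cause was not tested, except where a stricter fold or fewer libraries is the setting itself.

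Array weights gave 5 genes in naive cells, 4296 on day 3, 138 on DLL4 and 35 for the interaction. DESeq2 gave 7, 81 and 31 for naive, DLL4 and the interaction, and edgeR 0 on DLL4. With the first principal component of the residuals as covariate 5 naive and 2096 day 3 genes passed, and with all 22 naive and day 3 libraries in 1 fit 6 naive genes. On DLL4 pseudocount 0.5 and limma without trend gave 0 genes each (1154 at an unadjusted p under 0.05 before), and no filter 21. For BATF in WT cells no filter gave 465 and limma without trend 417, which gave 2 for the interaction. Under rescaling to the same total and quantile normalization no called list changed the sign of its median. Requiring 2-fold as well left 147 genes on day 3, 126 in KO Empty, 42 in WT Batf, 75 in KO Batf, 318 in KO Batf against WT Empty and 3 for the interaction. Without KO Batf replicate 4 and KO Empty replicate 3, apart on principal components, 1234 passed in WT Batf and 43 for the interaction.

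Of the lists called, an estimated correlation left 0 in naive cells, 0 on day 3, 0 on DLL4, 1 in KO Empty, 2 in WT Batf, 3 in KO Batf, 1 in KO Batf against WT Empty and 0 for the interaction. Counted over all lists tested and not only those called by camera, fry called 0 in naive cells, 3 on DLL4, 6 in WT Batf, 14 in KO Batf against WT Empty and 0 for the interaction. Its counts on day 3, in KO Empty and in KO Batf are not given here. With the estimated correlation the adjusted p of the day 3 sets in limma's camera was 0.0636 (lower set, DLL4), 0.292 and 0.405 (WT Batf), 0.0801 (higher set, KO Batf) and 0.21 (higher set, interaction). With stricter sets (adjusted p under 0.01 and 2-fold) the lower set was called in naive cells (median −0.11) and in KO Batf (−0.23), and the higher set on DLL4 (−0.16). With an estimated correlation these were at adjusted p = 0.0715, 0.185 and 0.0415, and the lower set on DLL4 at adjusted p = 0.0193, so both DLL4 calls held with the stricter sets. The lower set's interaction reversed to −0.0448. At an adjusted p under 0.01 the overlap tests passed for 28 genes higher in KO Empty and in KO Batf, and for 18 lower in KO Empty and higher in WT Batf.

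Leaving out each library in turn gave 0 to 0 genes in naive cells (279 at an unadjusted p under 0.05), 632 to 1402 on day 3, 0 to 232 on DLL4, 1393 to 2165 in KO Empty and 370 to 1008 in WT Batf (370 to 661 for libraries of its 2 groups), highest without KO Batf replicate 4 in both. It gave 953 to 1807 in KO Batf, 2783 to 3639 in KO Batf against WT Empty and 4 to 35 for the interaction. In naive cells Batf ranged from −0.21 to 0.0859 (above 0 without WT replicate 2, and 0.04 without KO replicate 3) and Notch2 from −0.0612, without WT replicate 3, to 0.53.

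Replicate numbers do not pair the samples by the labels. With the number as a replicate block, 2 genes passed in naive cells, 1222 on day 3 and 0 on DLL4, and no other total of genes or lists called moved by more than 1.5 times. The calls of G1/S genes in WT Batf (adjusted p = 0.0503) and of ribosomal protein genes in KO Batf (adjusted p = 0.0501) were lost, and ribosome biogenesis was called downward on day 3 (adjusted p = 0.0149). Libraries correlated best with their own number in 3 of 6 cases in naive cells, 4 of 16 on day 3, 0 of 6 on DLL4 and 7 of 8 in KO Empty against WT Empty. Pairs of the same number correlated above 0.1 in 2 of 3 cases in naive cells (up to 0.77), 6 of 8 on day 3 (up to 0.647), 0 of 3 on DLL4 and 2 of 4 in KO Empty (up to 0.213).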

Other observations

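The fit of naive and day 3 libraries together and the other splits of the libraries were tests chosen only after results were seen.

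The naive and day 3 tables share a scale, and the step from naive to responding WT cells was tested in limma on all 22 libraries. Of 11746 genes 9179 passed, 4769 higher and 4410 lower on day 3. Il2ra went from 7.14 to 13729 normalized counts, granzyme B (Gzmb) from 92.3 to 39904.5 and Mki67 from 82.1 to 12816, and Rrm2 rose 157-fold. The naive and memory genes Tcf7 (21956 to 2147), Ccr7 (18557 to 1676) and Il7r (2614 to 299) fell. All 35 G1/S genes and all 35 mitotic genes rose (median log2 fold changes 4.21 and 6.77), with adjusted p = 0.0129 and adjusted p = 0.0332 with an estimated correlation. Of 34 effector genes 28 rose and 3 fell (median 2.73, adjusted p = 0.0332 with an estimated correlation), and of 28 naive and memory genes 24 fell and 2 rose (−2.58, adjusted p = 0.0245 with an estimated correlation). Of 37 interferon-stimulated genes 34 fell (−2.59, adjusted p = 0.137 with an estimated correlation). Markers of other cells moved too: 6 of 7 myeloid genes rose and none fell (3.27, adjusted p = 0.0441; adjusted p = 0.351 with an estimated correlation), and 10 of 14 B cell genes rose and 3 fell (1.76, adjusted p = 0.538). Naive cells came from lymph nodes and spleen and day 3 cells from spleen, so the step holds tissue and infection as well as activation.

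The difference between the KO effects at the 2 stages passed for 115 of the 10491 genes measured at both, 74 upward and 41 downward. Of 36 interferon-stimulated genes 9 differed upward and 0 downward in limma (median 0.89, adjusted p = 9.15e-21; adjusted p = 0.121 with an estimated correlation). Ifit1 stood at 2066 and 975 in naive WT and KO cells and at 53.1 and 90.6 on day 3, and Isg15 at 1151 and 526 and at 432 and 607.

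Other splits of the same libraries into groups of the same sizes were counted. On day 3, 1 of 100 splits drawn from 6435, the real one, gave 828 genes and the highest other 3. The real split also stood alone for KO Empty (1 of 35 splits, 1871 genes, highest other 3), WT Batf (1 of 35, 703, highest other 1), KO Batf (1 of 35, 1498, highest other 11) and KO Batf against WT Empty (1 of 35, 3499, highest other 128). A share of 1 in 35 is the smallest that 35 splits can give, so chance is unlikely in these comparisons but not excluded. The splits took no account of experiments. For the interaction 4 of 100 splits, the real one included, gave at least the real 12 genes. The highest other gave 118 genes, which points to a structure of the libraries that the groups do not name. The share of splits is under 0.05, but leaving out 1 library gave 4 to 35 genes, so the real count is not firm. The naive and DLL4 comparisons have 10 splits, too few for a share under 0.05. In naive cells the real split gave 0 genes (279 at an unadjusted p under 0.05 in limma), and the highest other gave 2028, with WT replicates 1 and 2 and KO replicate 1 on 1 side. On DLL4 2 of 10 splits, the real one included, gave at least the real 2 genes. The highest other gave 99, with OP9 replicate 1 and OP9-DLL4 replicates 2 and 3 on 1 side. Both point to a structure of the samples other than the groups.

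Without OP9 replicate 1 the co-culture gave 232 genes in limma, 201 higher and 31 lower on DLL4, of 11637 tested. Among them Dtx1 had a log2 fold change of 3.93, Gzmb 2.08 (adjusted p = 8.73e-06), Nt5e 2.05, Aldoc 2.05, Rsad2 1.90, Pkm 1.32, Il2ra 1.21 and Ifi27l2a 1.21. Zfp683 (−1.85, adjusted p = 0.0138) and Id3 (−1.02) fell. That the library stands apart was seen before it was left out, and why it does was not tested.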
